A study of Mus musculus with 6 samples.

How the data were processed

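Total RNA from the gastrocnemius, a calf muscle, of 12-week-old male mice was labelled with biotin and hybridised to an Affymetrix whole-transcript mouse gene array, 1 array per sample. There were 3 wild type samples and 3 samples from homozygous Sparc knockouts. Both genotypes carry the same strain label, B6;129S-Sparctm1Hwe/J, which names a mixed background of the B6 and 129S strains. The design text speaks of the muscle of each mouse, so each array was taken as 1 mouse. The labels do not say whether the mice were littermates, nor on which day the arrays were run.

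The deposited values are probe-set intensities on a linear scale, 1 column per array. They were summarised with RMA in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of each probe set. The deposited values ran from 1.59 to 13565.8 over 35556 probe sets, a range that fits a linear scale and not log2, with no detection calls, so no fold change below could be bounded by a background level. RMA fits all arrays together and shrinks differences between low values, so fold changes of dim genes can be understated. Depth has no meaning for these values, and the number of arrays limits the precision. The genome build behind the probe sets is not given in the sources used here. The 6 value columns were all used, and 0 columns were left unmapped.

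For the re-analysis, log2 of the deposited intensity was taken with no offset. The design had assumed log2 values. Probe sets were named from the platform annotation of the probe table, which can be old. There, 21789 probe sets had 1 gene symbol and 1621 had several, and 12146 probe sets of the value table were unnamed. Probe sets with several symbols were not used. Of the named probe sets, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols needed an update. That table served for names and for the order of genes along chromosomes only. For the 999 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used. Among the genes called below, 9 had several probe sets, and those of 2 of them, Polr1d and Zfp738 (named after their values were seen), differed in sign. Genes whose mean over all arrays lay under the 25th percentile of all probe sets (3.90 on the log2 scale) were left out, which removed 3451 of 19938 genes and left 16487 for testing.

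Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit on genotype, eBayes with a mean-variance trend, two-sided). P-values were adjusted with the Benjamini-Hochberg method, and 0.05 was the threshold. Errors given as ± after a group mean are SDs over 3 arrays, and those after a log2 fold change are the fit's moderated standard errors (SE). Fold changes are knockout over wild type unless called lower.

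Before the data were examined, 33 gene lists were fixed. They cover AMPK and insulin signalling, glucose, glycogen, fatty acid and lipid metabolism, the citric acid cycle, oxidative phosphorylation, mitochondrial biogenesis, collagens, matrix remodelling, the SPARC family, muscle fibre types, myogenic genes, atrophy, stress responses, the circadian clock, interferon response, and markers of other cell types. The 32 lists with at least 5 tested genes were compared with the other genes by camera, with a preset inter-gene correlation of 0.01. The erythroid list had 4 tested genes and was left out. Camera was repeated with a correlation estimated from the residuals of each list, and fry was run beside it. Fry asks whether a list's own genes changed and does not set them against the other genes. Its p-values are for a shared direction, unless its mixed test is named, which ignores direction. With 6 arrays the estimated correlation is itself imprecise. Adjusted p-values of lists are over the 32 lists. Counts of list members are given over all genes tested and adjusted over the list alone.

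The genes named were set by a rule. It took Sparc, the 12 largest increases and the 12 largest decreases past the threshold, and in each list up to 4 members past either adjustment with the largest change, or else the 2 with the smallest p. For a list past the camera threshold it added the 4 largest changes in the list's direction. Predicted genes, Riken clones and receptor families were not named unless one was the largest change. Genes named outside this rule are said to be chosen after their values were seen.

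The procedure was tested on 20 simulated data sets of 16487 genes for this comparison, drawn from the observed means and spread with 200 changed genes each. It recovered 37.9% of genes changed by 0.5 on the log2 scale, 97.8% of those changed by 1 and 99.8% of those changed by 2, and 6.16% of all calls were on unchanged genes. Each simulated gene had the same spread in both groups, whereas the observed median SD was 0.163 in knockouts and 0.0912 in wild types. These shares therefore hold for equal spread only. A list of independent genes shifted by 0.3 was found in 20 of 20 data sets, and 4 of 620 tests of unshifted lists passed. All simulated genes were independent, whereas the correlation estimated within the real lists ran from -0.14 (SPARC family) to 0.84 (macrophages). The simulation therefore does not show how often lists whose genes vary together pass by error.

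The alternatives were a replicate block, each array left out in turn, median centring, a second quantile normalization, no dim filter or one at the 50th percentile, averaged probe sets, other variance models, array weights, and every probe set in place of named genes. No pair of arrays held identical values. Correlations of log2 values were 0.990 to 0.992 between wild type arrays and 0.984 to 0.988 between knockout arrays.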

Results

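The study compared metabolic gene expression in gastrocnemius muscle of wild type mice and of mice lacking SPARC, a secreted matricellular glycoprotein that binds collagen. Microarray profiles of 3 wild type and 3 Sparc knockout males at 12 weeks of age were available, with 16487 named genes tested. The median deposited intensity per array was 40.5 to 44.7, with no split between the genotypes. Knockout arrays varied more among themselves than wild type arrays did. The median SD per gene was 0.163 in knockouts and 0.0912 in wild types on the log2 scale. The first principal component held 46.7% of the variance and separated all 3 knockouts from the wild types. Knockout array 2 lay nearest to the wild types, at 2.45 on that component against 26.5 and 19.8 for knockout arrays 1 and 3 and -16.8 to -15.8 for the wild types.

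Sparc transcript was 43.9-fold lower in the knockouts. Its log2 expression was 11.8 ± 0.072 (SD, n = 3) in wild type and 6.34 ± 0.47 (SD, n = 3) in knockout muscle, a log2 change of -5.46 ± 0.20 (SE; limma adjusted p = 2.08e-05). It had the smallest p of all genes. Every knockout array read between 5.83 and 6.74, above the filter for dim probe sets at 3.90. The labels do not say which part of the gene the allele removes, nor where the probe set lies in it, so the remaining signal cannot be assigned to a transcript.

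At an adjusted p of 0.05, 164 genes passed, of which 53 were higher and 111 lower in the knockouts, Sparc included. Of these, 14 were higher and 26 lower by more than 1 on the log2 scale. The knockout and wild type values did not overlap in 4114 of the 16487 genes, where 10% are expected by chance with 3 against 3. At an unadjusted p of 0.05, 3036 genes passed, 1345 higher and 1691 lower. With 1 wild type array left out, 27 to 32 genes passed (32, 30 and 27 without wild type arrays 1, 2 and 3), and 1017 passed without knockout array 2. Of the 81 genes that are named below by the rule and did not pass over all genes, 39 passed without knockout array 2. Conversely, over all alternatives and genes named by the rule, a call was lost 66 times. The losses given below for Sfrp4, Slc27a1 and Eci1 are only part of these, so calls given without a limit are not thereby stable.

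Gdpd3, a glycerophosphodiester phosphodiesterase family gene, rose most, 20.3-fold (log2 change 4.34 ± 0.20 SE, adjusted p = 8.04e-05). Its wild type level of 4.17, with 3.86 in wild type array 3, lies close to the dim filter at 3.90, so its fold may rest on background. The interferon-inducible p200 family genes Ifi202b and Ifi203 rose 6.77-fold and 2.31-fold, Ifi202b from a wild type level of 2.74, under the dim filter at 3.90, so that its fold rests on a level that can be background. Opn1mw, a cone opsin, rose 4.28-fold from a wild type level of 3.81, which lies under the filter too and can be background. Sfrp4, a secreted Wnt antagonist, rose 4.12-fold at an adjusted p of 0.0452, a call that was lost after median centring or a second quantile normalization, without the variance trend, with a robust one, and when any array other than knockout array 2 was left out. The chemokine Ccl8 rose 3.40-fold from a wild type level of 4.11, also close to the filter. Plpp4, a phospholipid phosphatase, and Lrrc3b rose 3.21-fold and 2.77-fold. Esco1, a cohesin acetyltransferase, rose 2.30-fold (with a smaller log2 change of 0.66 in its other probe set), and Smarca1, an ISWI chromatin remodeller, 2.14-fold. Hddc3 rose 2.12-fold, and Mrpl20, a protein of the large mitochondrial ribosomal subunit, 2.11-fold.

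AI506816 fell most after Sparc, by 13.3-fold (log2 change -3.73 ± 0.33 SE, adjusted p = 0.00187). The tripartite-motif genes Trim12a and Trim30d were 5.76-fold and 3.68-fold lower, with knockout levels of 4.23, close to the dim filter, and 3.78, under it. Fgfbp1, a carrier protein for fibroblast growth factors, was 3.86-fold lower, and Nxpe4 was 3.37-fold lower. Cd209a, a C-type lectin of myeloid cells, was 3.06-fold lower. Fbp2, the muscle fructose-1,6-bisphosphatase, was 3.03-fold lower (9.25 ± 0.29 against 7.65 ± 0.52, SD, n = 3 each, adjusted p = 0.0283). Adhfe1, a mitochondrial hydroxyacid-oxoacid transhydrogenase, and Rasd2, a Ras-family GTPase, were each 2.67-fold lower. Tmc7 was 2.60-fold lower. Pxmp2, a peroxisomal membrane channel, was 2.59-fold lower, and Npc1, the lysosomal cholesterol transporter, 2.37-fold lower.

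**Figure D1:**
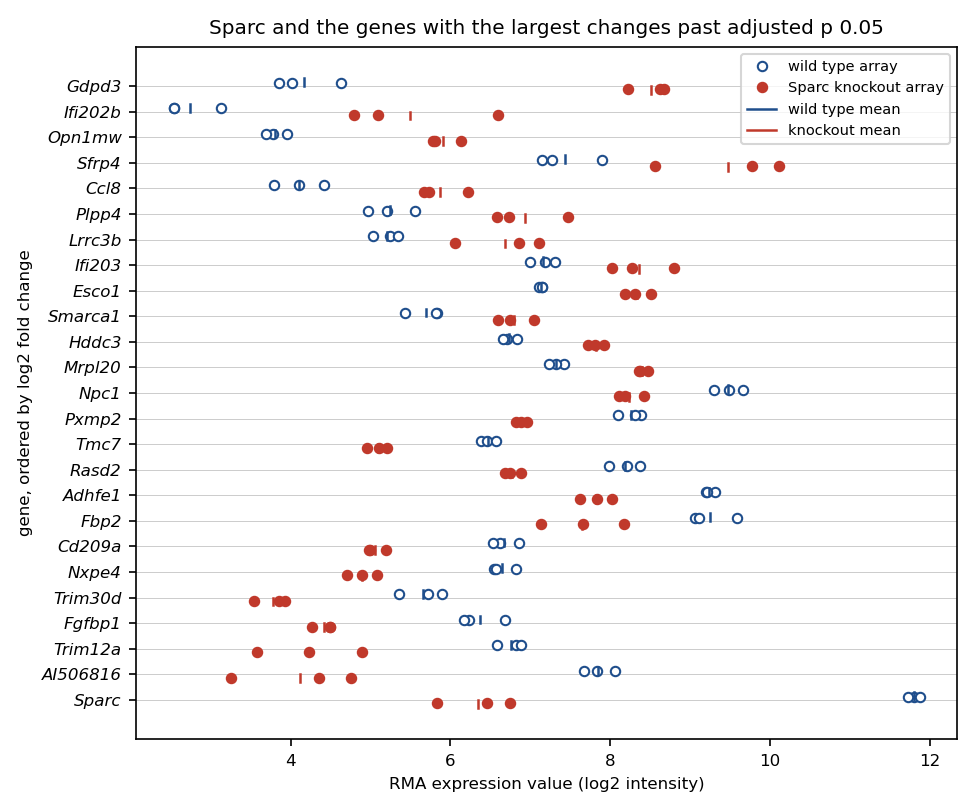
RMA expression (log2 intensity, x axis) of Sparc and the 24 genes with the largest changes past the threshold (y axis, ordered by log2 fold change), with open points for wild type arrays, filled points for knockout arrays and bars for the group means. The 3 knockout values lie apart from the 3 wild type values in every gene drawn, and the Sparc values fall from about 11.8 to 6.34.

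Genes of fatty acid uptake and oxidation were lower in knockout muscle. Of 27 members tested, 24 had a negative change, with a list mean of -0.23 on the log2 scale, and all 3 knockout arrays lay below all 3 wild type arrays in the list mean (-0.26 to -0.19 against -0.05 to 0.05). Over all genes, 2 members fell and none rose: Slc27a1, a fatty acid transport protein, was 1.53-fold lower (adjusted p = 0.0463), and Eci1, an isomerase needed for oxidation of unsaturated fatty acids, was 1.42-fold lower (adjusted p = 0.0426). Adjusted over the list alone, 9 members fell and 0 rose. These included Ucp3, a mitochondrial uncoupling protein, at -0.68 ± 0.17 (SE), and Mlycd, malonyl-CoA decarboxylase, at -0.52 ± 0.10 (SE). The list shifted downward by camera (adjusted p = 2.50e-06), but not with an estimated correlation (adjusted p = 0.714), and fry gave an adjusted p of 0.0442. Both Slc27a1 and Eci1 lost their calls after median centring, without the variance trend, and when any array other than knockout array 2 was left out. Slc27a1 also lost it after a second quantile normalization.

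**Figure D2:**
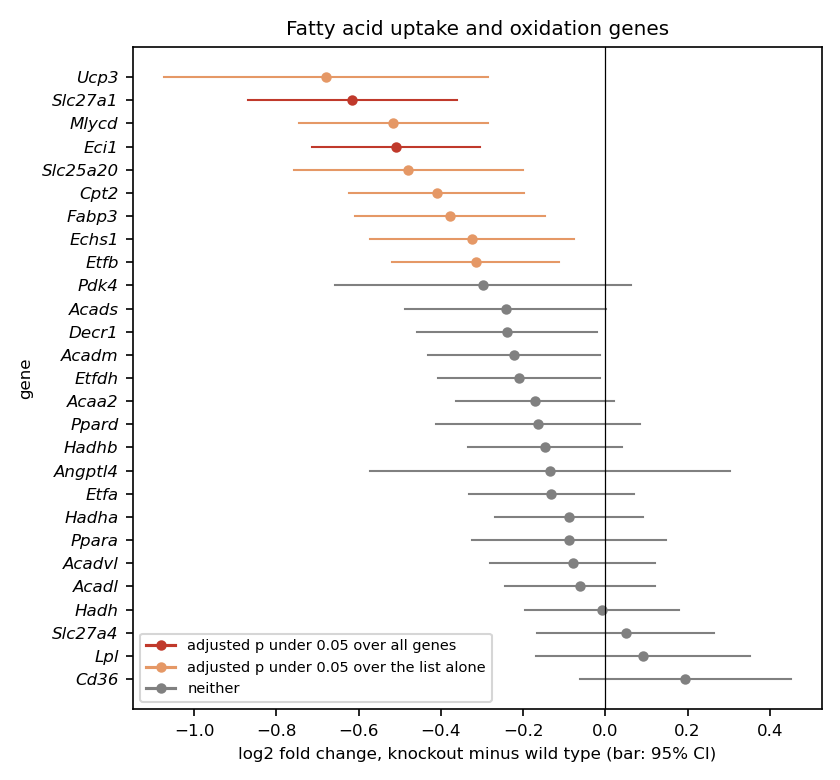
Log2 fold change of knockout over wild type (x axis, with the 95% confidence interval of the limma fit as bars) for the 27 genes of fatty acid uptake and oxidation that were tested (y axis). Only Slc27a1 and Eci1 pass the threshold over all genes, and 9 genes pass it when adjusted over the list alone.

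Genes of lipid synthesis and storage were also lower, with a negative change in 20 of 22 members and a list mean of -0.32. The wild type arrays differed among themselves, at -0.27, 0.07 and 0.20 in arrays 1, 2 and 3, so that array 1 lay at the level of the knockouts (-0.35, -0.27 and -0.34). None passed over all genes by limma, and 10 were lower and 0 higher at an unadjusted p of 0.05. Adjusted over the list alone, Dgat2, which makes triglycerides, fell (-0.73 ± 0.14 SE). Fasn, fatty acid synthase, had a change of -1.07 ± 0.38 (SE), Scd1, stearoyl-CoA desaturase, -0.58 ± 0.24 (SE), and Lpin1, a phosphatidic acid phosphatase, -0.49 ± 0.16 (SE), with adjusted p-values of 0.184, 0.256 and 0.168. Fasn was at -0.58 without wild type array 3, and Scd1 at -0.90 without wild type array 1. The list shifted downward by camera (adjusted p = 0.000102), but not with an estimated correlation (adjusted p = 0.747) or by fry (adjusted p = 0.384). Adipocyte markers had a mean change of -0.39 over 14 genes (camera adjusted p = 0.0518), with 0 past either adjustment and 2 lower and 1 higher at an unadjusted p of 0.05, and the wild type arrays differed among themselves, at -0.48 in array 1 against 0.23 and 0.25 in arrays 2 and 3. The 2 markers with the smallest p, Retn and Lep, had changes of -1.44 ± 0.37 and -1.15 ± 0.37 (SE; adjusted p = 0.102 and 0.157). The adipocyte list passed the threshold without wild type array 1, with a mean of -0.63, and also without the dim filter, with the stricter one and with array weights. By camera on ranks, a check added after the result was seen, it passed too (adjusted p = 0.0293). Wild type array 1 was low in both the lipid and the adipocyte list. The lower lipid genes therefore cannot be assigned to muscle fibres rather than to fat cells in the samples, which was not tested.

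Genes of glucose uptake and glycolysis had a mean change of -0.14 over 22 members, 17 of them negative. By limma 0 members passed over all genes or adjusted over the list alone, and at an unadjusted p of 0.05, 4 were lower and 1 higher. The list shifted downward by camera at an adjusted p of 0.0377, which was lost with an estimated correlation (adjusted p = 0.747), after a second quantile normalization, with the stricter dim filter, with averaged probe sets, without the variance trend, with array weights, and without wild type array 2 or 3 or knockout array 1 or 3. Its largest negative changes were in Pfkfb3 and Pfkfb4, regulators of phosphofructokinase activity, at -0.55 ± 0.23 and -0.36 ± 0.12 (SE), in the glucose transporter Slc2a3 at -0.34 ± 0.16 (SE), and in lactate dehydrogenase A (Ldha) at -0.30 ± 0.11 (SE), with adjusted p-values of 0.15 to 0.292. Knockout arrays 1 and 3 had list means of -0.23 and -0.19, and knockout array 2 was at 0.01, without which the mean was -0.21. Without knockout array 2, Pfkfb3 was at -0.85 and Slc2a3 at -0.53, and without knockout array 3 Slc2a3 was at -0.23.

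Genes around AMP-activated protein kinase (AMPK), the cellular energy sensor, did not pass the camera threshold as a list. They did pass fry's mixed test (adjusted p = 0.043). The mean change over 20 members was -0.13 (camera adjusted p = 0.0763), and 0 members passed over all genes or adjusted over the list alone. At an unadjusted p of 0.05, 7 members were lower and 2 higher. The smallest p belonged to Flcn, folliculin, at -0.48 ± 0.12 (SE; adjusted p = 0.107), and to Strada, a cofactor of the AMPK-activating kinase LKB1, at -0.32 ± 0.10 (SE; adjusted p = 0.139). The list passed without wild type array 1 (mean -0.17), without knockout array 2 (mean -0.18) and without the dim filter. Insulin signalling genes had a mean change of 0.03 over 24 members (camera adjusted p = 0.59). Irs2, an insulin receptor substrate, had a change of -0.41 ± 0.13 (SE; adjusted p = 0.143) and Cbl one of 0.29 ± 0.11 (SE; adjusted p = 0.228). Glycogen metabolism had a mean of -0.15 over 17 members (adjusted p = 0.113), with glycogenin (Gyg) at -0.43 ± 0.13 (SE) and the branching enzyme Gbe1 at 0.33 ± 0.10 (SE), adjusted p = 0.133 and 0.143. It passed without knockout array 2, with a mean of -0.23, and had a mean of -0.07 (adjusted p = 0.556) without knockout array 1.

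Central mitochondrial metabolism showed small mean changes that did not pass. Citric acid cycle genes had a mean of -0.10 over 21 members (camera adjusted p = 0.115), with Sdha at -0.34 ± 0.09 and Suclg1 at -0.32 ± 0.09 (SE). Oxidative phosphorylation genes had a mean of -0.08 over 40 members, 30 of them negative (adjusted p = 0.0501), with Ndufb3 at -0.39 ± 0.16 and Ndufa2 at -0.25 ± 0.11 (SE). Without knockout array 2 both lists passed, at means of -0.17 and -0.11. Oxidative phosphorylation also passed without wild type array 2 or 3, at means of -0.10 and -0.11, and after median centring, at -0.12. It passed as well without the dim filter and by camera on ranks (adjusted p = 0.0164), a check added after the result was seen. Its mean was -0.03 without wild type array 1 (adjusted p = 0.745) and -0.05 after a second quantile normalization (adjusted p = 0.526), and that of the citric acid cycle was -0.05 without knockout array 1 (adjusted p = 0.554). With array weights the means were -0.04 and -0.05. Mitochondrial biogenesis genes had a mean of -0.01 over 20 members (camera adjusted p = 0.78). They passed fry's mixed test (adjusted p = 0.043), with members that moved both ways. The coactivator Ppargc1a was at 0.44 ± 0.12 (SE; adjusted p = 0.122) and the mitochondrial transcription factor Tfb2m at -0.37 ± 0.13 (SE; adjusted p = 0.175).

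Extracellular matrix genes other than Sparc were higher in the knockouts. All 16 collagen genes tested and 26 of 29 matrix remodelling genes had positive changes, with list means of 0.63 and 0.61. No member passed over all genes by limma, and at an unadjusted p of 0.05, 8 collagens were higher and 0 lower, with 20 and 1 for the remodelling genes. Adjusted over the list alone, 4 collagens and 14 remodelling genes rose and 0 fell. These included Col12a1 (3.09-fold), Col8a1 (2.66-fold) and Col14a1 (2.01-fold) among the collagens. Among the remodelling genes they included the protease inhibitor Timp1 (2.43-fold), fibronectin (Fn1, 2.42-fold) and the thrombospondins Thbs4 (2.22-fold) and Thbs2 (2.06-fold). Postn, periostin, and Tnc, tenascin C, had mean changes of 2.12 ± 0.80 and 1.46 ± 0.58 (SE), with adjusted p-values of 0.204 and 0.227, which were 1.04 and 0.70 without knockout array 3. Col1a2 was at 0.71 ± 0.22 and Col5a2 at 0.94 ± 0.35 (SE). Both lists shifted upward by camera (adjusted p = 2.50e-06 and 1.78e-09), and neither did with an estimated correlation (adjusted p = 0.747 and 0.739). Neither passed by fry (adjusted p = 0.384 and 0.295). The size differed between knockout arrays: the remodelling list stood at 0.79, 0.22 and 0.83 above the wild type mean in knockout arrays 1, 2 and 3, and the collagens at 0.56, 0.18 and 1.14. Without knockout array 3 the collagen mean was 0.37 (camera adjusted p = 0.000239), with Col8a1 at 0.94, Col1a2 at 0.45 and Col5a2 at 0.48. Within the SPARC family itself, adjusted over the list alone, Fstl1 and Sparcl1 rose (1.62-fold and 1.35-fold) and Smoc2 fell (1.55-fold lower). Over all genes, 0 of 6 passed. The list did not pass by camera (mean 0.04, adjusted p = 0.721) but did by fry's mixed test (adjusted p = 0.0161).

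Macrophage markers were also higher. All 14 had positive changes, with a mean of 0.53. Over all genes 0 passed by limma, 8 were higher at an unadjusted p of 0.05, and 8 rose when adjusted over the list alone, among them Cd68 (1.99-fold), lysozyme (Lyz2, 1.80-fold) and the complement genes C1qb and C1qc (1.63-fold each). The list shifted upward by camera (adjusted p = 6.61e-06), but not with an estimated correlation (adjusted p = 0.747) or by fry (adjusted p = 0.396). It stood at 1.07 in knockout array 1 against 0.31 and 0.21 in knockout arrays 2 and 3, and without knockout array 1 its mean was 0.26, with C1qb and C1qc at 0.39 and 0.37. Tendon markers had a mean of 0.54 over 10 genes (camera adjusted p = 0.00136). The adjusted p was 0.747 with an estimated correlation and 0.426 by fry. Comp was at 1.02 ± 0.34, tenomodulin (Tnmd) at 0.99 ± 0.33 and Kera at 0.78 ± 0.38 (SE), and Thbs4 alone rose when adjusted over the list. The tendon markers stood at 1.15 in knockout array 1 and the call was lost without it (mean 0.23, with Comp, Tnmd and Kera at 0.59, 0.55 and 0.29). Pericyte and smooth muscle markers had a mean of 0.28 over 12 genes, all positive, and lay between 0.26 and 0.31 in every knockout array (camera adjusted p = 0.000307, and adjusted p = 0.425 with an estimated correlation, with 0.0401 by fry). Pdgfrb and Cspg4 rose when adjusted over the list alone (log2 changes of 0.54 ± 0.12 and 0.38 ± 0.10, SE), and Acta2 and Tagln were at 0.48 ± 0.17 and 0.37 ± 0.15 (SE). Without knockout array 3, Acta2 was at 0.30.

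**Figure D3:**
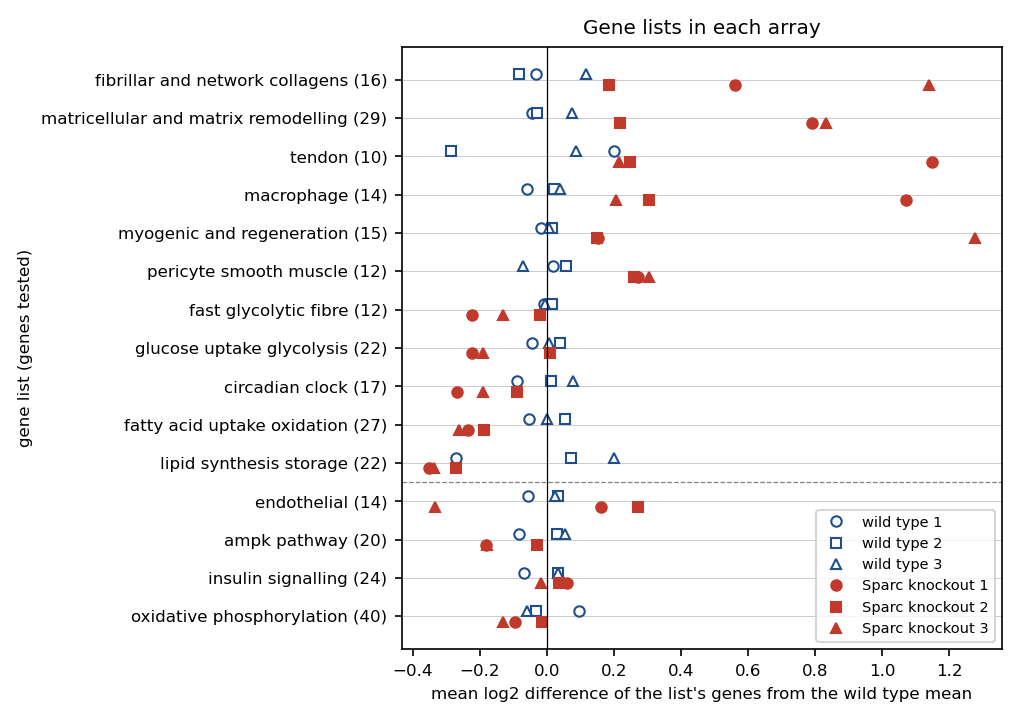
Mean log2 difference of each gene list from the wild type mean (x axis) in each of the 6 arrays, with open symbols for wild type, filled symbols for knockout and the symbol's shape for the replicate number. The y axis names the list and the number of genes tested; lists above the dashed line passed the camera threshold, and the 4 below it are shown for comparison. Knockout array 1 stands highest for macrophage and tendon markers (1.07 and 1.15) and knockout array 3 for the myogenic list (1.28).

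Markers of fast glycolytic fibres had a mean of -0.13 over 12 genes (camera adjusted p = 0.00737, and adjusted p = 0.747 with an estimated correlation), with 0 members past either adjustment and 3 lower and 1 higher at an unadjusted p of 0.05. Mylk2 was at -0.48 ± 0.15, Myoz1 at -0.26 ± 0.09, Actn3 at -0.25 ± 0.09 and Tnni2 at -0.16 ± 0.08 (SE). The call was lost without knockout array 1 (mean -0.08) and after a second quantile normalization (mean -0.08). Slow and oxidative fibre genes did not pass as a list (mean -0.13 over 13 genes, adjusted p = 0.757), and the knockouts differed, at -0.31, -0.63 and 0.56 in arrays 1, 2 and 3. Without knockout array 3 the list passed, with a mean of -0.47, and without knockout array 2 its mean was 0.13 (adjusted p = 0.211). Its member Myl3, a ventricular and slow myosin light chain, fell 2.34-fold over all genes (adjusted p = 0.0256).

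The myogenic and regeneration list had a mean of 0.53 over 15 genes, 14 of them positive (camera adjusted p = 0.00175). The adjusted p was 0.747 with an estimated correlation and 0.426 by fry. Actc1, cardiac alpha-actin, which is also made in developing muscle, rose 1.68-fold over all genes (adjusted p = 0.0147). Adjusted over the list alone, Ankrd1, a stress-responsive sarcomere protein gene, and Cdkn1c, a cell cycle inhibitor, rose as well (3.04-fold and 1.32-fold). Embryonic myosin Myh3 and the fusion gene Mymk had mean changes of 1.57 ± 0.88 and 1.14 ± 0.75 (SE; adjusted p = 0.39 and 0.473). Those means came from knockout array 3, where Myh3 read 9.07 and Mymk 8.60 against 4.71 to 5.36 and 5.16 to 5.58 in the other 5 arrays. Without that array the list mean was 0.15, with Ankrd1 at 1.04, and the call was lost.

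Clock genes had a mean of -0.18 over 17 members, 14 of them negative (camera adjusted p = 0.00438, and adjusted p = 0.747 with an estimated correlation), with 0 past either adjustment and 8 lower at an unadjusted p of 0.05. Arntl was at -0.48 ± 0.15, Ciart at -0.46 ± 0.15, Nr1d1 at -0.46 ± 0.17 and Nfil3 at -0.29 ± 0.10 (SE). Ciart was at -0.31 without wild type array 3, and Nr1d1 at -0.29 without knockout array 3. The list lost its call without knockout array 1 (mean -0.14). The remaining lists did not pass. Fibroblast and fibro-adipogenic progenitor markers had a mean of 0.13 (adjusted p = 0.154), with Lama2, a laminin chain, up 1.68-fold over all genes (adjusted p = 0.0179) and, adjusted over the list alone, Mfap5 and Pi16 up 1.56-fold and 1.54-fold (Pi16 at a log2 change of 0.40 without knockout array 1) and Smoc2 down. Endothelial markers had a mean of 0.03 (adjusted p = 0.72), with Egfl7 at 0.21 ± 0.13 and Cldn5 at -0.21 ± 0.13 (SE). Without knockout array 3 both lists passed, with means of 0.24 and 0.22. Interferon response genes had a mean of -0.13 (adjusted p = 0.36; -0.20 without knockout array 1 and -0.08 without knockout array 2), with Rsad2 and Bst2 lower by 1.93-fold and 1.74-fold when adjusted over the list alone. Immediate early genes had a mean of -0.08 (adjusted p = 0.85), with the nuclear receptor Nr4a3 up 1.58-fold over all genes (adjusted p = 0.0419) and Ier3 up 1.32-fold adjusted over the list alone.

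Heat shock genes (mean 0.11, adjusted p = 0.59) held Hsp90aa1 at 0.56 ± 0.16 and Hspb7 at 0.54 ± 0.15 (SE). Endoplasmic reticulum stress genes (mean 0.06, adjusted p = 0.36) held Hsp90b1 at 0.58 ± 0.16 and Pdia4 at 0.48 ± 0.19 (SE). Atrophy genes (mean 0.06, adjusted p = 0.85) held the metallothionein Mt2 at 0.99 ± 0.28 and the ubiquitin ligase Trim63 at -0.44 ± 0.14 (SE). Neuromuscular junction genes (mean 0.16, adjusted p = 0.139) held the acetylcholine receptor subunits Chrnd and Chrnb1 at 0.49 ± 0.17 and 0.43 ± 0.13 (SE). With 1 array left out none of these 4 lists passed, but their means moved. They ran from 0.03 to 0.20 for heat shock and from 0.0017 to 0.11 for atrophy (without knockout arrays 3 and 2), from 0.02 to 0.09 for endoplasmic reticulum stress (lowest without knockout array 1), and from 0.09 to 0.24 for the neuromuscular junction (without knockout arrays 3 and 1). Schwann cell markers (mean 0.07, adjusted p = 0.55) held Pmp22 at 0.31 ± 0.20 and Ncmap at 0.25 ± 0.14 (SE). Without knockout array 2 these 2 genes were at 0.15 and 0.099, and without knockout array 3 at 0.56 and 0.38. Neutrophil, lymphocyte and mast cell markers had means of 0.08, 0.13 and -0.0015 (adjusted p = 0.53, 0.46 and 0.52), with 0.04 for neutrophils without wild type array 2. Adjusted over their lists alone, Csf3r, Cd4 and Tph1 rose 1.49-fold, 1.78-fold and 1.43-fold. The median and the mean differed in sign for the heat shock, endothelial, atrophy, lymphocyte and mast cell lists, and in the mast cell list the test pointed upward with a mean below 0. Without knockout array 3 the mast cell list passed, with a mean of 0.40. Of the 32 lists, 11 passed with the preset correlation (6 higher and 5 lower) and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry 2 passed, the fatty acid list and that of pericytes and smooth muscle. Fry's mixed test passed 5, which were these 2 with the SPARC family, AMPK and mitochondrial biogenesis lists. Other splits of the 6 arrays into 3 and 3 gave up to 17 lists with the preset correlation, so that count alone does not mark the genotypes.

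The strain label names a mix of B6 and 129S, and a targeted allele can carry flanking sequence of the strain it was made in, so genes near Sparc on chromosome 11 were compared with the rest of that chromosome. Of 239 genes within 10 Mb on either side, 41 had an unadjusted p under 0.05 (17.2%), against 187 of the 1184 other genes of the chromosome (15.8%; odds ratio 1.10, two-sided Fisher's exact test, p = 0.629). By the same exact test, it was 28 of 133 within 5 Mb (21.1%, p = 0.106) and 75 of 460 within 20 Mb (16.3%, p = 0.877). A difference between the genes around Sparc and the rest of the chromosome was not detectable with these arrays.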

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

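Camera on ranks was added after the result was seen, and the other alternatives given here were chosen beforehand. The Sparc change passed the threshold under every alternative run, from -5.66 to -5.20 with 1 array left out. The 164 genes called kept their sign in every alternative that fitted named genes and in which they were present, but their number moved. It was 103 after median centring (26 higher and 77 lower, 100 shared with the 164), 329 with array weights, 570 at an adjusted p of 0.10 and 3036 at an unadjusted p of 0.05, and 27 to 1017 with 1 array left out. The low end came without wild type array 3 and the high end without knockout array 2 (423 higher and 594 lower), and the cause was not tested. The share of called genes that were higher was 32.3%, against 43.8% when every probe set was tested (49 higher and 63 lower). The same-numbered arrays showed no sign of pairing: their deviations from the group means correlated at 0.0088, 0.082 and -0.020, and 2 of 6 arrays correlated best with their own number. The labels do not say whether the numbers pair mice, and groups of 3 cannot exclude it. With the replicate number as a block, 123 genes passed (59 higher and 64 lower, 91 shared with the 164) and 15 lists, and these were the 11 with AMPK (adjusted p = 0.0379), glycogen (0.0328), oxidative phosphorylation (0.0345) and adipocytes (0.0143), and the share of genes within 10 Mb of Sparc with an unadjusted p under 0.05 was 14.2%, below that of the rest of the chromosome (14.7%). Against the other chromosomes the share near Sparc (17.2%) was also the lower one (18.7%), and it was 12.6% to 22.2% with 1 array left out. The 11 lists past the threshold became 0 with an estimated correlation, 13 on ranks, and 7 to 15 with 1 array left out (7 without knockout array 1). The 13 on ranks were the 11 with oxidative phosphorylation and adipocytes (camera on ranks, adjusted p = 0.0164 and 0.0293). Fry, which asks a different question, passed 2, and 5 by its mixed test. Lists whose mean turned sign were not past the threshold with all arrays. After median centring the means were -5.31e-05 for the SPARC family, -0.014 for insulin signalling and -0.0084 for endothelial markers. The mean was 0.0023 for mitochondrial biogenesis after a second quantile normalization and 0.0091 for mast cells without the dim filter. With 1 array left out, means ran from -0.0057 to 0.064 for the SPARC family, -0.0073 to 0.048 for insulin signalling, -0.032 to 0.014 for mitochondrial biogenesis, -0.47 to 0.13 for slow fibres, -0.22 to 0.066 for immediate early genes, -0.028 to 0.24 for fibroblasts, -0.086 to 0.22 for endothelium, -0.0026 to 0.15 for Schwann cells and -0.24 to 0.40 for mast cells. The causes were not tested. Without detection calls, changes of genes near the dim filter at 3.90 have no lower bound on their level.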

Other observations

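The lists in this paragraph and the next were chosen after the data were seen, so their p-values are not independent evidence, and they were adjusted over these 9 lists only. They were refitted with each array left out, a check added after the result was seen. Genes that break down branched-chain amino acids were lower in knockout muscle, with a mean change of -0.43 over 18 genes (camera adjusted p = 4.42e-13, and adjusted p = 0.143 with an estimated correlation). Over all genes 2 fell, Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase (-0.76 ± 0.09 SE, adjusted p = 0.0102), and Mccc1, a subunit of methylcrotonyl-CoA carboxylase (-0.75 ± 0.12 SE, adjusted p = 0.0283). Adjusted over the list alone, 17 fell, among them Bcat2, the mitochondrial branched-chain aminotransferase (-0.54 ± 0.12 SE), and Ivd, isovaleryl-CoA dehydrogenase (-0.60 ± 0.14 SE). Mitochondrial ribosome genes had a mean of -0.25 over 77 members (adjusted p = 2.16e-15, and adjusted p = 0.234 with an estimated correlation). Over all genes Mrpl55, Mrps14 and Mrpl54 fell (-0.83, -0.71 and -0.57) and Mrpl20 rose. Adjusted over the list alone, 32 fell and Mrpl20 rose. Mitochondrial import genes had a mean of -0.22 over 23 members (adjusted p = 6.16e-06, and adjusted p = 0.234 with an estimated correlation), with Timm17a down over all genes (-0.81 ± 0.10 SE).

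Proteasome genes had a mean of -0.16 over 39 members (camera adjusted p = 1.84e-06, and adjusted p = 0.067 with an estimated correlation), with Psmd6 down over all genes (-0.72 ± 0.09 SE). Cytosolic ribosome genes had a mean of -0.09 over 49 members (adjusted p = 0.0247, and adjusted p = 0.658 with an estimated correlation), with Rpl34 down over all genes (-1.16 ± 0.19 SE). The knockout arrays stood at 0.03, -0.26 and -0.04, and the call was lost without knockout array 2 (mean -0.0015) or wild type array 1 (mean -0.02). Complement genes were higher, with a mean of 0.54 over 12 members (adjusted p = 1.84e-06, and adjusted p = 0.262 with an estimated correlation), and 7 rose when adjusted over the list alone, among them C3ar1 (1.00 ± 0.27 SE) and C4b (0.86 ± 0.20 SE), with 0 past over all genes. The list shares C1qa, C1qb and C1qc with the macrophage list and stood at 1.06, 0.31 and 0.26 in knockout arrays 1, 2 and 3. Without knockout array 1 its mean was 0.29 (adjusted p = 0.000214), and C3ar1 was at 0.64. Lysosomal cathepsins had a mean of 0.28 over 15 members (adjusted p = 0.021, and adjusted p = 0.251 with an estimated correlation), and 5 rose when adjusted over the list alone, including Ctse (1.28 ± 0.35 SE), Ctsk (1.15 ± 0.31 SE) and Ctss (0.86 ± 0.27 SE). They stood at 0.51, 0.14 and 0.20, and the call was lost without knockout array 1 (mean 0.17, adjusted p = 0.155), where Ctse and Ctss were at 0.81 and 0.57. Chemokine genes (28 members, mean 0.09, adjusted p = 0.252) and MHC class II genes (6 members, mean 0.06, adjusted p = 0.394) did not pass, and their means were 0.04 and 0.01 without knockout array 1.

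The first pattern weighed is the higher matrix remodelling, macrophage and myogenic lists. The tests of tendon carry-over, fibre share and single arrays were chosen after the result was seen, as was the direction test of neighbouring pairs in the next paragraph. With 1 knockout array left out, the mean of the remodelling list stayed at 0.505 or more (0.614 with all arrays), which argues against a single array as its source, while the macrophage mean dropped to 0.256 without knockout array 1 and the myogenic mean to 0.151 without knockout array 3, so each of these may rest largely on 1 muscle. Tendon carried over at dissection cannot be told apart from a change in the muscle, because the myogenic mean, which tendon would not bring, was 0.526 ± 0.375 (SE between arrays), and 8 tendon-only markers and the collagens had means of 0.518 ± 0.358 and 0.628 ± 0.284. That myogenic mean came largely from knockout array 3, so it says little about carry-over in knockout array 1. Tendon markers stood at 1.15, 0.25 and 0.21 in knockout arrays 1, 2 and 3, and the collagens at 0.56, 0.18 and 1.14. The collagens of knockout array 3 thus rose without a like rise in tendon markers, though this rests on 1 array. A lower share of muscle fibre would raise the markers of all other cell types alike. Macrophage markers exceeded the mean of 9 other types by 0.431 ± 0.183 (SE between arrays, with 0.79, 0.18 and 0.32 in the knockouts against -0.01 to 0.01). They exceeded adipocyte markers by 0.918 ± 0.308 and fibroblast markers by 0.401 ± 0.120. Against every other type the difference was under 2 errors: tendon -0.0088 ± 0.169, endothelial 0.495 ± 0.254, pericyte 0.248 ± 0.284, neutrophil 0.450 ± 0.270, lymphocyte 0.393 ± 0.258, Schwann cell 0.457 ± 0.279 and mast cell 0.529 ± 0.304. Macrophages were picked after their rise was seen, and it may rest largely on knockout array 1. The test thus argues only weakly against a lower fibre share as the whole cause. Regeneration in every knockout muscle, a biological candidate explanation, was not settled either, as 2 of 3 knockout arrays lay above every wild type array in both Myh3 and Myh8, although all 3 lay above them in the mean of the myogenic list (0.15, 0.15 and 1.28 against -0.02 to 0.01), and an effect of genotype stays open. Myh3 read 5.36, 5.11 and 9.07 in knockout arrays 1, 2 and 3 against 4.71 to 5.18 in the wild types. Knockout array 1 thus lay only just above them, and a large Myh3 rise was seen in knockout array 3 alone.

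The second pattern is the large changes on chromosomes other than 11, where among 38 genes past the threshold with a change over 1 on the log2 scale, 6 pairs lay within 10 tested genes of each other, against up to 3 in the central 95% of 10000 random draws of as many tested genes (permutation test, p = 6e-04), which is what segments of the B6 and 129S strains that differ between the groups could give. The pairs were Dusp23 with Ifi203 and with Ifi202b, Ifi203 with Ifi202b, Trim12a with Trim30d, Lrrc3b with Oxsm, and Esco1 with Npc1, where Dusp23 and Oxsm were named after their values were seen. Probes shared between paralogs would leave no pairs of different families and would move both members the same way. Yet 4 pairs of different families remained (up to 3 in the central 95% of the draws, permutation test, p = 0.0138). All 4 had members that moved in opposite directions, which argues against shared probes within them. However, 2 of the 4 join Dusp23 to the paralogs Ifi203 and Ifi202b, and are not separate if those share probes. Their count is thus weak evidence of an excess. A count added after the result was seen took the 36 genes over 1 in every probe set. It leaves out Esco1 (0.66 in its other probe set) and Zfp738, and 5 pairs remained. Of these, 3 were of different families, which is not above the draws' central 95% of up to 3 (permutation test, p = 0.048). Among all 150 genes past the threshold on these chromosomes there were 40 pairs, 34 of them of different families (permutation test, p = 1e-04 for each count). For the 2 pairs of one family among the large changes, whose members moved the same way, shared probes stay open. Some genes named above as pathway members stood in these 40 pairs. Psmd6, Timm17a, Mrpl20 and Eci1 each had a called neighbour of a different family. Whether the wild types were littermates is not given in the labels used here. An effect of Sparc loss on all these genes and one of the background therefore stay open.

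The third pattern is the lower clock list. Muscles collected at another clock time could move genes of opposite phase apart. The 4 genes of the Arntl phase and 9 of the Dbp phase had means of -0.21 and -0.16, a difference of -0.0467 ± 0.0824 (SE between arrays). No divergence was thus seen. The genes of a group do not all peak at the same hour, however, so both means can fall together at some times. The test therefore does not settle whether the collection time differed. An effect of genotype was not tested beyond the comparison itself.

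The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 164 genes and the highest of the others 0, so 1 of 10 gave as many. For the gene lists the real split gave 11, the highest of the others 17, and 5 of 10 gave as many. The number of lists past the camera threshold therefore does not tell the genotypes from other groupings of these arrays.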
